A study of Rattus norvegicus with 4 samples.

How the data were processed

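RNA from vessels of male rats was hybridised to 1-colour Agilent arrays, with 1 array for each of 4 groups: WT control, WT Ang II, KO control and KO Ang II. Total RNA was labelled with Cy3, per the labels' protocols. All 4 arrays lay on 1 slide with 1 scan time, per the file headers. Slide and scan thus did not separate the groups and no block was fitted. Positions on the slide were 1 for WT control, 2 for WT Ang II, 3 for KO control and 4 for KO Ang II. Position therefore cannot be told apart from group, and median background along it was 22, 21, 20 and 19. Whether dissection, treatment or RNA preparation differed in batch between groups is not given in the sources used here.

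The intensity values were deposited as scanner output with 58717 spots per array other than controls, for 45598 probes. The processed signal is an intensity after background subtraction and spatial detrending within the array, per the file headers, and is not normalized between arrays. Median pixel signals and the error of each processed signal are intensities as well, and the flags for signal well above background, saturation and outlier spots are 0 or 1, per the file headers. The submitters' processing notes name Agilent Feature Extraction 12.1.1.1, whereas the file headers give version 10.7.1.1, so the version is not settled. The authors' deposited value table holds log2 values. Each of its columns equalled log2 of the processed signal plus a constant within 0.01 for 98.3% to 98.4% of probes, with medians of 2.29, 2.22, 2.27 and 2.11 for WT control, WT Ang II, KO control and KO Ang II. Its software and the reason for its constants are not given in the sources used here.

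Spots flagged as outliers were left out (301 to 372 per array) and the spots of a probe were averaged. Probes with no unflagged spot on some array, 4 in all, were dropped. The log2 processed signal minus the array's 75th percentile was the main value, where that percentile was 58.7, 62.5, 47.3 and 52.1 in the order above. Fewer than 50% of probes were well above background, so a percentile over probes detected on all arrays was added as an alternative after seeing the data. Replicate spots of a probe had a median SD of 0.0646 to 0.0746 on the log2 scale, which is technical precision only. The number of arrays limits the precision of every comparison.

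Probe accessions were matched without versions to a table of rat genes of the GRCr8 assembly, which was used for names only. The array design's own build differs, so no coordinates are given. A gene name was found for 21107 probes (16580 genes) and none for 24487, of which 9048 were well above background on at least 1 array. A gene took the value of its brightest probe by mean over the 4 arrays, among probes well above background on at least 1. Where a gene was well above background on only 1 of the 2 arrays compared, the dim side was set to the higher of its own value and the lowest value of any probe well above background on that array. The result is a bound, written as "at least".

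With 1 array per group the single comparisons used a size rule of 2-fold and no test. Named genes were chosen by a rule fixed before the data were examined: Prkcb, then per comparison the 10 largest in each direction measured on both arrays and the 3 largest bounds in each direction, up to 4 members of a described list, and members of the renin-angiotensin, kinase C and NADPH oxidase lists. Some were left out for length. Genes with only a provisional symbol were counted and not named.

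Gene lists, 43 in all, were fixed at the same time. A list needed 5 members well above background on at least 2 arrays. Its median was placed among 10000 random lists matched in 20 bins of mean expression and was taken to stand apart under percentile 2.5 or over 97.5. Such percentiles describe these arrays, and genes that vary together from sample to sample would move them without any treatment. Between 30 and 34 lists were summarised per comparison, so about 1.5 to 1.7 would stand apart by chance if genes varied independently. Lists that stood apart numbered 5 higher and 1 lower for Ang II in WT, 7 and 6 for Ang II in KO, 4 and 7 for KO against WT without Ang II, 2 and 11 with it, and 5 and 10 for the difference of responses.

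The additive fit of genotype and treatment used limma 3.58.1 in R 4.3.3 over 9387 genes well above background on at least 2 arrays, with Benjamini-Hochberg adjustment at 0.05 and with camera at a preset correlation of 0.01 and with an estimated one. It took dim values as read, with no bound, and had 1 residual degree of freedom and 3.13 prior degrees of freedom. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

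The steps were tested on simulated data with 200 changed genes among 9387. For Ang II in WT the size rule recovered 27 of 50 genes changed 2-fold and 50 of 50 changed 4-fold, with 234 false calls. The simulated spread came from the additive fit, whose residual is the interaction, so it holds any real difference of responses as well as noise. For Ang II over both genotypes limma recovered 0 of 100 genes at 2-fold and 0 of 100 at 4-fold when these were the only sizes. When 8-fold and 32-fold changes were mixed in, it recovered 2 of 50 at 2-fold, 35 of 50 at 4-fold, 47 of 50 at 8-fold and 50 of 50 at 32-fold, with 5 false calls. Of 200 random lists of 15 unchanged genes, 8 stood apart, and all 200 did with 0.5 added to each member. The simulated genes varied independently, so this does not cover lists whose members vary together.

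Alternatives were quantile normalization, the median of detected probes, the deposited value table, stricter and no filters on dim probes, the mean of a gene's probes, size rules of 1.5-fold and 3-fold, trended robust variances, a single-factor fit and an adjusted threshold of 0.1. The planned normexp on mean signals was run on median signals with an offset of 50, since the files used here hold no mean signal column. This change was made after seeing the data.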

Results

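Gene expression was measured in vessels of male rats on 1-colour microarrays, with 4 arrays in 4 groups. Wild-type (WT) Wistar rats were set against rats with a deletion of protein kinase C beta (KO). Vessels of each genotype were either left untreated or treated for 24 h with angiotensin II (Ang II), the pressor peptide of the renin-angiotensin system. Each group held 1 array, so differences between single arrays carry no p-value and no replicate check. The labels name 4 rats per genotype, and whether RNA of several rats was pooled is not given in the sources used here. The share of probes well above background was 43.6% for WT control, 43.5% for WT Ang II, 40.7% for KO control and 41.5% for KO Ang II, and no spot was saturated. Named genes well above background on at least 1 array numbered 9966.

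Prkcb, the gene of the deleted kinase, was read by 2 probes. The probe with replicate spots gave a processed signal of 14.8 in WT control and 18.0 in WT Ang II. Its signal was 1.94 in KO control and 1.89 in KO Ang II, where it was not well above background. Prkcb was thus at least 2.11-fold lower in KO without Ang II and at least 2.54-fold lower with it, and its log2 ratio for Ang II in WT was 0.19. The other Prkcb probe read 12.2 in WT Ang II, its only signal well above background, with 8.27 in WT control, 1.90 in KO control and 1.73 in KO Ang II. Whether these probes lie inside the deleted part of the gene is not given in the sources used here.

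The first comparison asked how WT vessels differed after Ang II. Genes of inflammation were higher with Ang II on the single arrays compared. Ccl5, a chemokine that attracts T cells, was 3.68-fold higher, the neutrophil chemokines Cxcl1 and Cxcl2 were 3.22-fold and 2.92-fold higher, and the cytokine Il6 was 2.99-fold higher. The interferon-induced membrane protein Bst2 was 3.17-fold higher and the antigen peptide transporter Tap1 was 3.34-fold higher. Edn1, the precursor of the vasoconstrictor endothelin-1, was not well above background in WT control and was at least 8.55-fold higher with Ang II.

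The cytokine and chemokine list had a median log2 ratio of 0.80 in this comparison, with 20 of 21 measured members above 0 and 9 at least 2-fold higher. The interferon response list had a median of 0.93, with all 18 measured members above 0 and 6 at least 2-fold higher, led by Bst2 (1.67), Usp18 (1.48), Ifit3 (1.45) and Gbp5 (1.44). Targets of NF-kB and adhesion molecules had a median of 0.61 over 10 members, all above 0, with Traf1 at 1.11 and Nfkbia and Nfkb2 at 0.86 each. All 3 medians lay at percentile 100 among random lists matched on expression. The antioxidant list was higher by a smaller amount, with a median of 0.31 (percentile 99.96) and Slc7a11, the cystine transporter, at 0.83. Oxidative phosphorylation genes had a median of 0.18 (percentile 98.7), which lay inside the random range with normexp, with quantile normalization and with the mean of a gene's probes. Macrophage markers stood beside these groups with a median of 0.18, inside the range of random lists (percentile 92.7). Haemoglobin genes, too few for a list median, stood at 0.84 (Hba-a1), 1.18 (Hba-a2) and 0.73 (Hbb-b1) for Ang II in WT and at 0.49, 0.54 and 0.62 in KO.

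Further genes with the largest higher values in WT were Gdf15, a stress-induced growth factor, at 1.90, Acod1, the enzyme that makes itaconate at 1.82 and the interleukin subunit Il23a at 1.62. As bounds, Ttc21a was at least 14.3-fold and Rnd1 at least 7.04-fold higher. Lower values were led by Rgs5, a regulator of G-protein signalling found in pericytes and smooth muscle, at -2.93. Ak5 (-2.90), the imprinted transcript H19 (-2.67), Kctd16 (-2.26), Cxcl14 (-1.96), Sfrp4 (-1.88) and Myoc (-1.81) followed. Cd163, a scavenger receptor of resident macrophages, was at -1.66 and Lyve1, a marker of lymphatic endothelium and some macrophages, at -1.64. Ccl21 was lower by at least 5.61-fold, Or8b101c by at least 5.19-fold and Ephx4 by at least 3.91-fold. White adipocyte markers had a median of -0.49 over 7 members (percentile 0.18). Rgs5, Ak5 and Kctd16 were high on the WT control array alone, which the comparison of KO with WT without Ang II also uses: the scaled log2 signal of Rgs5 was 0.13 there and -2.79, -3.47 and -2.41 on WT Ang II, KO control and KO Ang II.

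In all, 198 genes were at least 2-fold higher and 98 at least 2-fold lower with Ang II among 9819 compared in WT, of which 105 and 48 were measured on both arrays. These counts are not evidence of change by themselves, since each group has 1 array. In simulated arrays at the spread limma estimated, 200 of 9387 genes were changed and none was given as a bound. There 234 unchanged genes passed the size rule for this comparison, more than the 105 and 48 measured genes together. That spread holds any real difference of responses and dim values as read, so 234 is no estimate of the false calls here. Background correction by normexp left 29 higher and 8 lower. Higher and lower genes numbered 163 and 122 when scaled to the 75th percentile of detected probes, and 169 and 120 when scaled to their median.

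**Figure D1:**
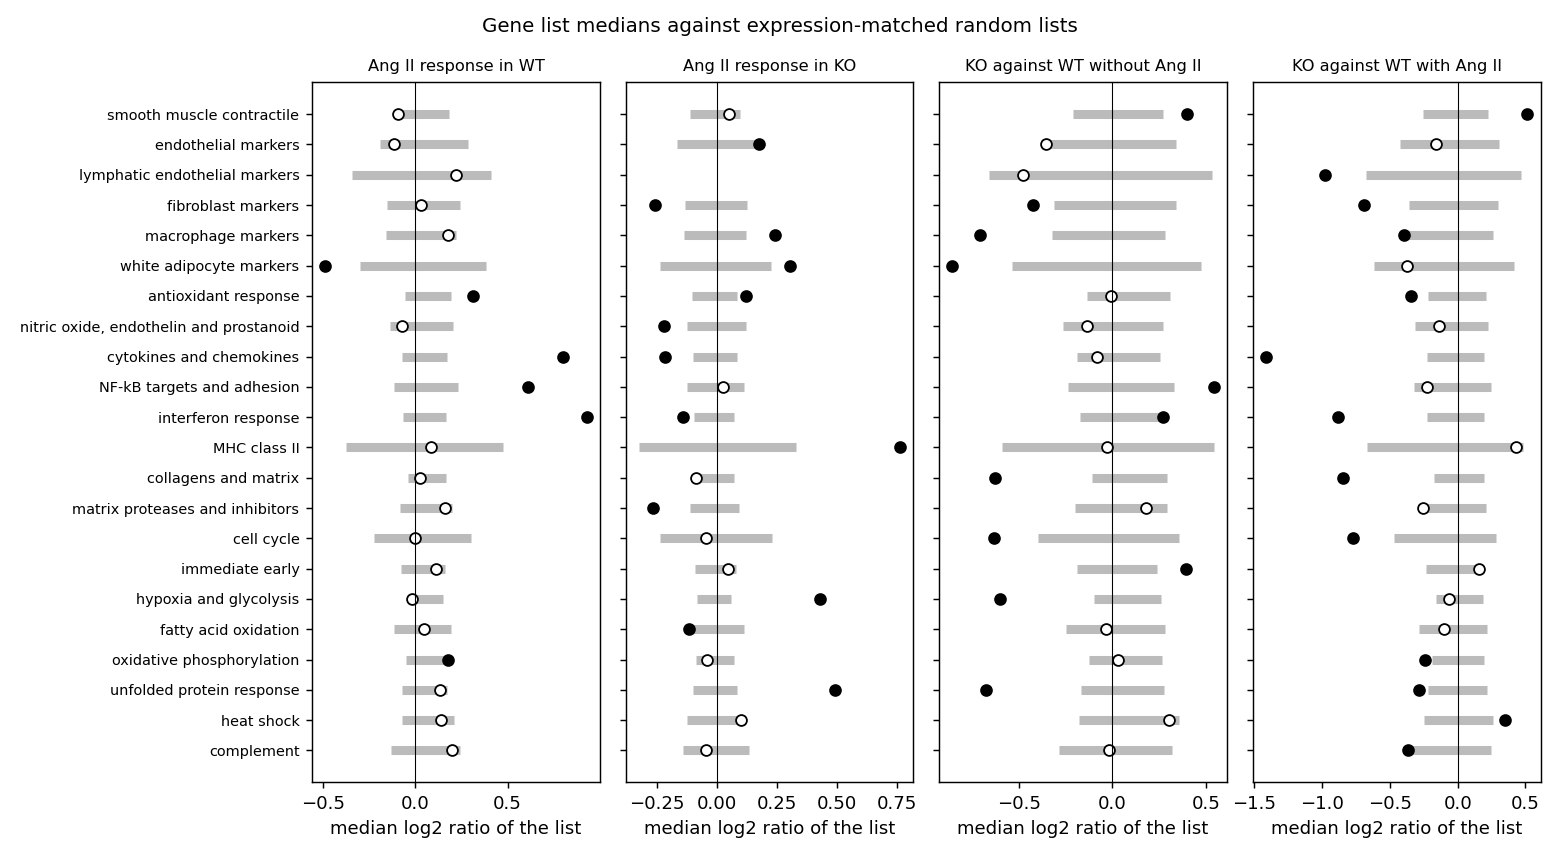
Median log2 ratio of each gene list (points, horizontal axis) in the 4 comparisons, for lists that stood apart from random lists in at least 1 of them. Grey bars give the central 95% of medians of 10000 random lists matched on expression, and filled points lie outside it; the interferon response list sits at 0.93 for Ang II in WT and at -0.14 for Ang II in KO.

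The second comparison asked the same of KO vessels. Genes of hypoxia and glycolysis and of the unfolded protein response were higher with Ang II there. All 21 measured hypoxia and glycolysis genes lay above 0, with a median of 0.43, and the largest were Ankrd37 (0.97), the mitochondrial protein Bnip3 (0.84), the glycolytic regulator Pfkfb3 (0.76) and the collagen hydroxylase P4ha2 (0.72). All 17 measured genes of the unfolded protein response lay above 0 as well, with a median of 0.49. Sesn2 stood at 0.90 or more, as a bound, Creld2 at 0.88, Sdf2l1 at 0.73 and Dnajb9 at 0.66. None of the members of either list measured on both arrays reached 2-fold. Both lists stood at percentile 100, and both had their lowest level of the 4 arrays in KO control.

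MHC class II genes, which present antigen, had a median of 0.76 over 5 members in KO (percentile 100), with RT1-Bb at 0.86 and RT1-Da at 0.83. Macrophage markers (median 0.24, percentile 99.97), endothelial markers (median 0.18, percentile 98.1) and white adipocyte markers (median 0.30, percentile 99.4) were higher beside them. With normexp the endothelial and adipocyte medians lay inside the random range, as did the endothelial one with quantile normalization. Fibroblast markers were lower, with a median of -0.26 (percentile 0.02). The cytokine and chemokine list had a median of -0.22 (percentile 0.01), with 5 of 21 members above 0, and the interferon response list one of -0.14 (percentile 0.09), with 4 of 18 above 0. Matrix proteases and their inhibitors had a median of -0.27, with the collagenase Mmp13 at -1.42 and the stromelysin Mmp3 at -1.20, while the macrophage elastase Mmp12 was 2.14-fold higher. Genes of nitric oxide, endothelin and prostanoid signalling had a median of -0.22 (percentile 0.02), with the inducible nitric oxide synthase Nos2 at -1.32. Nos2, Mmp13 and Mmp3 read highest on the KO control array. They stood at 1.54, 1.09 and 0.54 for KO against WT without Ang II, and at -0.76, -0.02 and -0.25 with it. The antioxidant list was at 0.12 (percentile 99.5) and fatty acid oxidation at -0.12 (percentile 2.25), both inside the random range with normexp.

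The largest single higher values in KO with Ang II were Pnn at 1.39, Clec4a3 at 1.17, Fam107a at 1.14, Mex3b at 1.12 and Tbx1 at 1.11. The largest lower values were Lgals5 at -2.27, Uncx at -2.20, Oxct2b at -2.15, the preadipocyte factor Dlk1 at -2.14 and Ptges3l1 at -1.96. As bounds, Irs3 was at least 6.48-fold higher, Pdilt at least 15.4-fold lower and Arsl at least 12.2-fold lower. Pdilt, Arsl and Ptges3l1 were high on the KO control array alone, so they also appear among the higher genes of KO against WT without Ang II. Of 9281 genes compared, 41 were at least 2-fold higher and 130 at least 2-fold lower, with 11 and 42 of them measured on both arrays. The split was 55 higher and 102 lower with quantile normalization and 0 higher and 4 lower with normexp. Of 6 genes past 2-fold with another probe measured, the second probe had the same sign in 3 and was past 2-fold in 1, against 7 and 5 of 7 for Ang II in WT.

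The third comparison set the Ang II responses of the genotypes against each other, over 8600 genes well above background on all 4 arrays. The cytokine and chemokine list had a median difference, KO response minus WT response, of -1.10, with 11 of 21 members at least 2-fold lower. The interferon response list had the same median of -1.10 over 17 members, all below 0, with 10 at least 2-fold lower. All 10 NF-kB and adhesion genes lay below 0, with a median of -0.69. That list was lowest on the WT control array, with a median log2 level, relative to each gene's mean over the arrays, of -0.42 against 0.25 on WT Ang II, 0.14 on KO control and 0.06 on KO Ang II, and for KO against WT with Ang II its median was -0.22 (percentile 8.08). The largest differences downward were Bst2 (-2.43), Ccl5 (-2.34), Nos2 (-2.30), Ptges3l1 (-2.12), the apoptosis gene Bid (-2.08), Dusp13b (-2.06) and Tap1 (-2.02). Ptges, the inducible prostaglandin E synthase, stood at -1.98. Upward, the largest were Klhdc8b (2.31), the Wnt antagonists Sfrp4 (1.98) and Sfrp1 (1.73), Tbx1 (1.90), Cited2 (1.81), Pcp4l1 (1.72) and the muscle intermediate filament gene Des (1.70). Des was high on the WT control array, which KO against WT without Ang II also uses. Its scaled log2 signal was 3.73 there and 2.22, 2.62 and 2.81 on WT Ang II, KO control and KO Ang II. Hypoxia and glycolysis (median 0.46) and the unfolded protein response (median 0.28) stood at percentile 100 in the other direction, and MHC class II genes had a median of 0.58 (percentile 98.5). Beside them, fibroblast markers had a median of -0.33 (percentile 1.80), inside the random range with quantile normalization. Endothelial markers had one of 0.25 (percentile 97.9), which turned slightly negative with normexp.

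A size of at least 2-fold in this difference was reached by 109 genes upward and 247 downward, and with normexp by 20 and 50. The 97 genes at least 2-fold higher in WT, measured on all arrays, had a median of 1.16 there and of -0.07 in KO, and 42 of them lay above 0 in KO. No gene was at least 2-fold higher in both genotypes, against 0.113 for independent lists, and 1 was at least 2-fold lower in both, against 0.14. Across genes, which are not independent replicates, the responses had Pearson's r of -0.083 and Spearman's rho of -0.092. With 1 array per group the difference has no test.

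**Figure D2:**
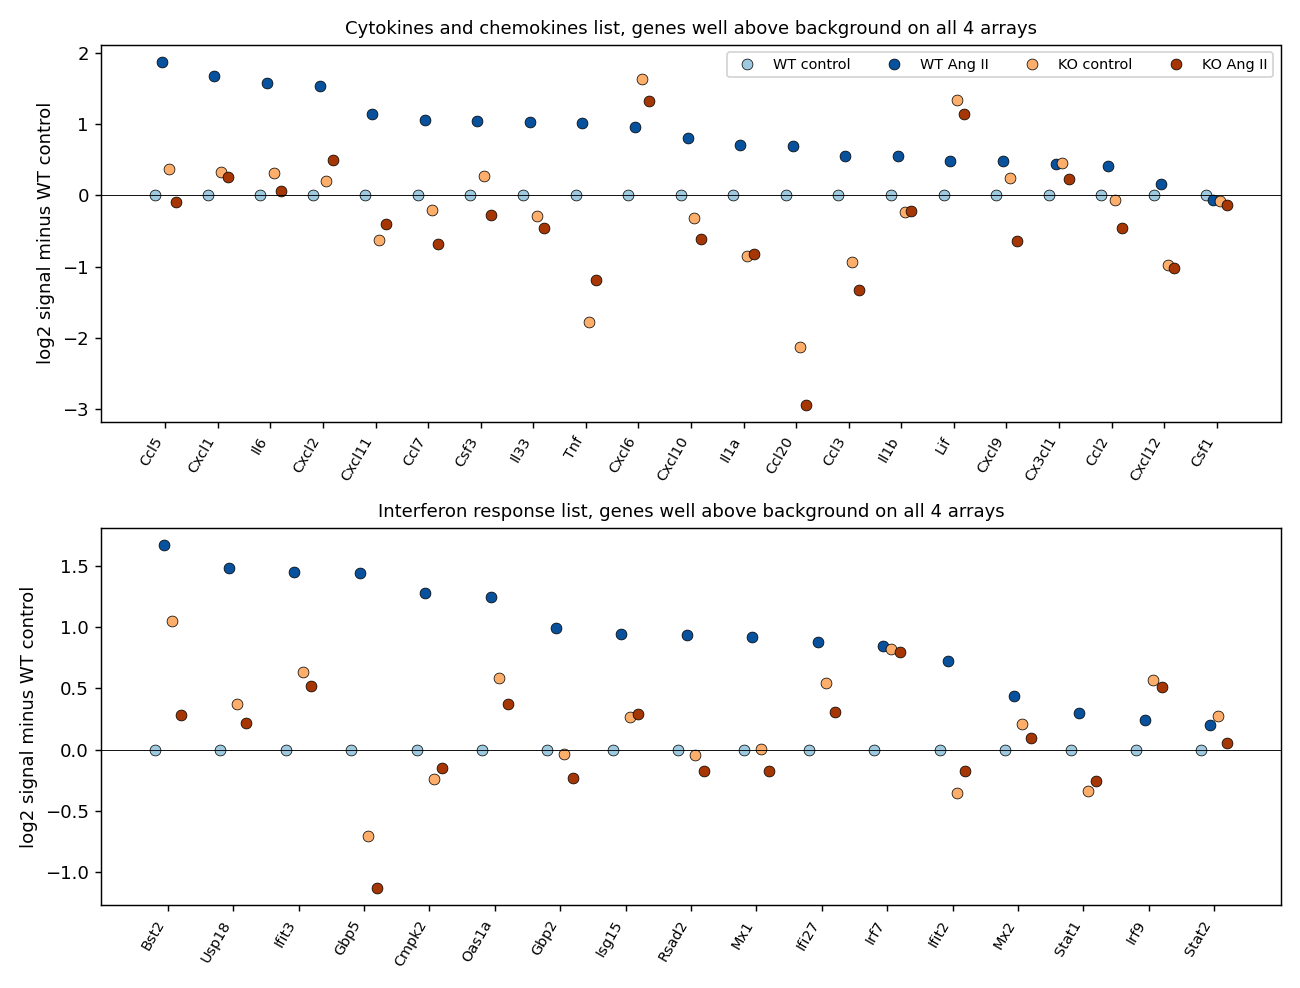
Log2 signal minus the WT control value (vertical axis) of each cytokine and chemokine gene (top) and each interferon response gene (bottom) well above background on all 4 arrays, with 1 point per array coloured by group. WT Ang II is the highest of the 4 for Ccl5, Cxcl1 and Il6 and for Bst2, Usp18 and Ifit3, while KO Ang II lies below WT control for Gbp5 and Ccl20.

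The fourth comparison set KO against WT vessels without Ang II. Collagen and matrix genes were lower in KO, with a median of -0.63 over 18 members, 15 of them below 0 and 7 at least 2-fold lower. The matrix cross-linking enzyme Loxl2 stood at -2.38, Col8a1 at -1.62, Col1a1 at -1.52 and Col3a1 at -1.45. Over the comparisons without and with Ang II, Col1a1 averaged -1.65 on its brightest probe and -0.56 on a second probe. Smooth muscle contractile genes were higher, with a median of 0.40 and 15 of 17 above 0, among them Cnn1 (2.22-fold higher), Myl9 (2.07-fold higher) and Tpm2 (0.81), while Des stood at -1.11. Markers of other cells were lower beside them, with medians of -0.71 for macrophages (percentile 0.01), -0.42 for fibroblasts (percentile 0.69) and -0.85 for white adipocytes (percentile 0.04). Endothelial markers had a median of -0.35 (percentile 2.84). Lymphatic endothelial markers had one of -0.48 (percentile 7.1), inside the random range, with 2 of 5 above 0.

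Cell cycle genes had a median of -0.63 over 12 members without Ang II (percentile 0.14), with the ribonucleotide reductase subunit Rrm2 at -2.83 and the proliferation marker Mki67 at -1.44. The kinase Cdk1 was at least 9.54-fold lower, and the cyclin Ccna2 stood at -2.18 as a bound. Hypoxia and glycolysis (median -0.60, percentile 0) and the unfolded protein response (median -0.68, percentile 0) were lower too. NF-kB and adhesion genes (median 0.54, percentile 99.9), immediate early genes (median 0.39, percentile 99.97) and interferon response genes (median 0.27, percentile 98.3) were higher.

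The largest single values were Dusp13b at 2.65, Inhba, an activin subunit, at 2.25, Ptges3l1 at 2.23, Pdha2 at 2.02 and Prp2 at 2.01. Downward they were Sfrp4 at -3.05, Rrm2 at -2.83, Cxcl14 at -2.61, Tbx1 at -2.58, Wnt16 at -2.56 and Serinc2 at -2.42. As bounds, Pdilt was at least 19.4-fold and Arsl at least 15.3-fold higher, and Reln at least 14.7-fold, H19 at least 12.8-fold and Akr1c15 at least 11.6-fold lower. Among 9613 genes, 280 were at least 2-fold higher and 389 lower, and with normexp 25 were higher and 89 lower. Of 50 genes past 2-fold with another probe measured, the second probe had the same sign in 38 and was past 2-fold in 17.

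The fifth comparison set KO against WT vessels with Ang II. Cytokine and chemokine genes were lower in KO, with a median of -1.41 and 15 of 21 at least 2-fold lower. Ccl20, which attracts dendritic cells and lymphocytes, stood at -3.64, Tnf at -2.21, Ccl5 at -1.97 and Ccl3 at -1.89. The interferon response list had a median of -0.88, with 7 of 18 at least 2-fold lower and Gbp5 at -2.57. Both lists were highest on the WT Ang II array, which Ang II in WT and the difference of responses also use. Their results in these comparisons are thus not independent. The cytokine list's median log2 level, relative to each gene's mean over the arrays, was -0.03 on WT control and 0.95 on WT Ang II. It was -0.25 on KO control and -0.53 on KO Ang II. The interferon median, over 17 members, was -0.22, 0.69, -0.11 and -0.18 in the same order. Collagen and matrix genes had a median of -0.84, with 8 of 18 at least 2-fold lower. They were led by Col1a1 at -1.78, whose second probe changed less as given above, and Sparc at -1.74. Contractile genes were again higher in KO, with a median of 0.51 (percentile 100) and 15 of 17 above 0.

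Beside them, markers of fibroblasts (median -0.69, percentile 0.04), macrophages (median -0.40, percentile 2.17) and lymphatic endothelium (median -0.98, percentile 0.40) were lower, and those of white adipocytes stood at -0.37 (percentile 13.0) and of endothelium at -0.16 (percentile 27.7). The lymphatic median was the value of Prox1, and Lyve1, Reln and Flt4 were bounds. Lyve1 and Reln were well above background in WT only, so they could come out only as lower in KO. Skeletal muscle markers had a median of 0.07 here and of 0.10 without Ang II, both inside the random range. With quantile normalization the macrophage median lay inside the random range. Cell cycle genes had a median of -0.77 (percentile 0.07), inside the range with the mean of a gene's probes. Smaller medians outside the random range were those of the antioxidant list (-0.34), oxidative phosphorylation (-0.24), the unfolded protein response (-0.28), complement (-0.36) and heat shock (0.35). With normexp those of the antioxidant list, oxidative phosphorylation and complement lay inside it, as did complement with quantile normalization. Single lower values were led by Ccl20, Ttc21a (-2.92), the acute phase protein gene Orm1 (-2.91), Ubd (-2.84), Car4 (-2.74) and the scavenger receptor Olr1 (-2.65). Higher values were led by Gpatch4 (2.17), Slmap (2.04), Rasal2 (1.90), Cend1 (1.82) and the NADPH oxidase gene Nox4 (1.81). As bounds, Cytl1 was at least 8.45-fold higher, Cdk1 at least 8.63-fold lower and Edn1 at least 6.78-fold lower. Among 9658 genes, 188 were at least 2-fold higher and 502 lower, and with normexp 18 were higher and 137 lower. The second probe had the same sign for 44 of 65 genes past 2-fold and was past 2-fold for 16.

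The genotype differences without and with Ang II, which share no array, had Pearson's r of 0.598 and Spearman's rho of 0.587 across 8600 genes. Whether the control and Ang II vessels of a genotype came from the same rats is not given in the sources used here. If they did, differences between rats or preparations would enter both comparisons. At least 2-fold in both were 37 genes upward, against 2.49 for independent lists, and 100 downward, against 9.55. Of the sum of squares of the 3 contrasts over these genes, genotype took 68.2%, the interaction 17.2% and Ang II 14.7%.

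**Figure D3:**
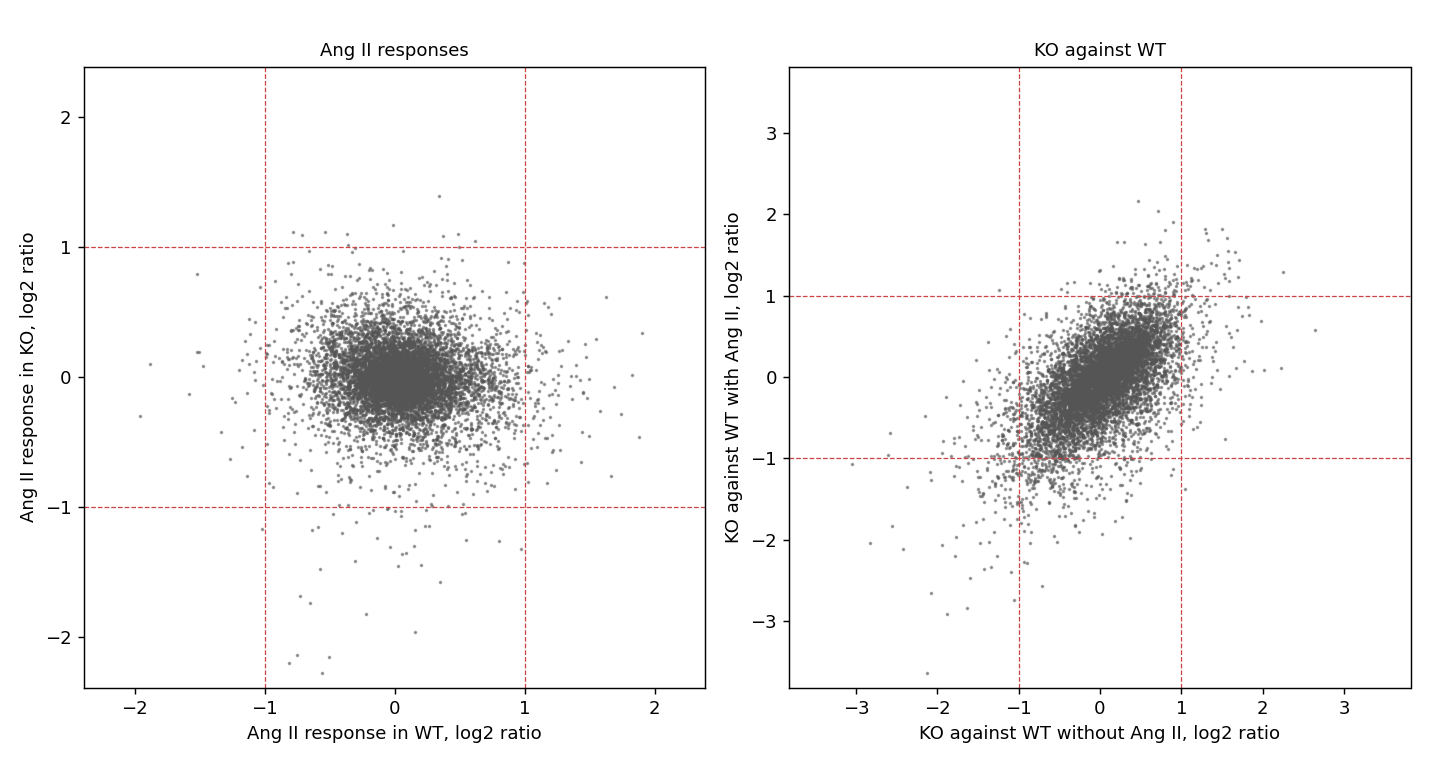
Log2 ratios of 8600 genes well above background on all 4 arrays, with Ang II responses of WT (horizontal) against KO (vertical) on the left and KO against WT without (horizontal) and with Ang II (vertical) on the right. Dashed lines mark 2-fold; Pearson's r is -0.083 on the left and 0.598 on the right.

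Members of the angiotensin and kinase pathways were followed in every comparison. Agtr1a, the main vascular Ang II receptor, was at least 3.29-fold lower in KO without Ang II and at least 3.66-fold lower with it, and stood at -0.01 for Ang II in WT. Atp6ap2, the prorenin receptor, was at 0.77 for Ang II in WT and -1.13 for KO against WT with Ang II. Among NADPH oxidase genes, Nox4 was at -0.72 for Ang II in WT and 0.29 in KO, and the small GTPase Rac2 was at -1.02 and -1.18 for KO against WT without and with Ang II. Of the other kinase C genes, Prkch stood at -0.58 and -0.63 in these comparisons, Prkcd at 0.24 and -0.07 and Prkci at -0.15 and -0.26. The medians of the renin-angiotensin and NADPH oxidase lists lay within the random range in every comparison, as did that of the kinase C list in the 3 comparisons where it was summarised.

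The additive fit was the only test across genes. In it the genotypes stand in for replicates of Ang II and the treatments for replicates of KO. Its residual therefore does not come from replicate samples of a group. With limma and Benjamini-Hochberg adjustment, 0 of 9387 genes passed for Ang II (191 higher and 169 lower at an unadjusted p under 0.05) and 0 passed for KO (1020 higher and 1433 lower). The smallest adjusted p for KO was 0.0709, and the trended robust version of limma called 558 genes higher and 715 lower. For KO, 3 genes were called lower in a single-factor fit and 8 with the deposited values. The fit has 1 residual degree of freedom, and in simulated arrays it recovered 0 of 100 genes changed 4-fold by Ang II when 4-fold was the largest change, so 0 calls do not show that genes were alike. With larger changes in the mix, it recovered 35 of 50 changed 4-fold.

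Gene sets were tested in the same fit with camera at a preset correlation. Dim values entered this fit as read and not as bounds, so a gene dim in KO can fall further here than in the comparisons. The cell cycle gene Ccnb2, with bounds of -0.43 and -0.33 for KO against WT without and with Ang II, entered KO control at -4.39. For Ang II over both genotypes, the unfolded protein response (median 0.29, adjusted p = 5.22e-05), hypoxia and glycolysis (median 0.24, adjusted p = 0.000925), interferon response (median 0.41, adjusted p = 0.000925), cytokines and chemokines (median 0.28, adjusted p = 0.00878) and NF-kB and adhesion (median 0.33, adjusted p = 0.0121) rose. Each had adjusted p = 0.959 with an estimated correlation. In KO alone the interferon, cytokine and NF-kB medians were -0.14, -0.22 and 0.025, so for these lists the effect averages a higher WT value with a KO value below or near 0. The hypoxia and unfolded protein response lists stood the other way round, with medians of -0.015 and 0.13 in WT, both inside the random range, against 0.43 and 0.49 in KO. For KO over both treatments, contractile genes (median 0.35, adjusted p = 0.00141) and heat shock genes (median 0.28, adjusted p = 0.0196) rose. Collagens and matrix (median -0.74, adjusted p = 0.000165), cell cycle (median -1.04, adjusted p = 0.000165), macrophage markers (median -0.55, adjusted p = 0.0036), unfolded protein response (median -0.47, adjusted p = 0.0036), cytokines and chemokines (median -0.60, adjusted p = 0.00447), white adipocyte markers (median -0.49, adjusted p = 0.0465) and kinase C genes, a list that includes Prkcb itself (median -0.40, adjusted p = 0.0471), fell. Each had adjusted p = 0.895 with an estimated correlation. In the kinase C list Prkcb, the deleted gene, entered as read at -4.61 in KO control and -4.78 in KO Ang II. In WT control and WT Ang II it entered at -1.99 and -1.79. The list was not tested without Prkcb, so its camera result is no evidence that the other kinase C genes fell. The cytokine and chemokine median was -0.08 for KO against WT without Ang II, inside the random range, and -1.41 with it. The version with an estimated correlation rests on the 1 residual degree of freedom. Its smallest unadjusted p over all lists was 0.233 for Ang II and 0.151 for KO. The estimates, from that 1 degree as well, were -0.059 for contractile, -0.026 for macrophage and 0 for heat shock genes. None exceeds the preset 0.01. With 1 degree, however, each gene enters such an estimate only by the sign of its residual, which is the interaction. The estimates therefore cannot show whether members vary together from sample to sample. For the other called lists the estimates ran from 0.030 (cell cycle) to 1 (interferon response, NF-kB and adhesion). For none of the called lists was the loss of significance split between the correlation and the low degree of freedom. Adjusted over the list alone, 10 of 18 collagen and matrix genes and 8 of 12 cell cycle genes were lower in KO, against 0 over all genes tested. On the same basis 4 macrophage, 4 unfolded protein response, 6 cytokine and chemokine, 3 kinase C and 2 white adipocyte genes were lower, and 2 heat shock genes and 1 cytokine gene were higher. Among lists of cell markers that camera did not call, 5 of 8 fibroblast, 3 of 5 lymphatic endothelial and 2 of 10 endothelial markers were lower in KO and 1 fibroblast marker higher. Of 6 skeletal muscle markers, also not called, 1 was higher and 1 lower in KO. For the contractile list and the lists called for Ang II the count was 0, while 2 lymphatic endothelial markers were lower and 1 NADPH oxidase gene higher for Ang II.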

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

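Every test of an explanation in this part was chosen after the result it bears on had been seen. Differences between the genotypes' Ang II responses were not tested, since each response rests on 1 array per group.

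The genotypes moved in opposite directions with Ang II in the interferon response list, with a median log2 ratio of 0.9286 in WT and -0.1429 in KO, and in the cytokine and chemokine list, with 0.8011 and -0.2164. Scaling of the arrays is argued against as the cause of the higher WT values: a constant per array cancels in the rise of the interferon median above that of all genes in WT, which was 0.890, and with quantile normalization and normexp, which can move it, the lower value was 0.831 (95% interval 0.731 to 1.20, members resampled). With normexp the cytokine value fell from 0.763 to 0.574 (0.351 to 0.853) in WT and was -0.181 in KO (-0.271 to -0.0394), while the interferon value in KO was -0.0570 (-0.150 to 0.0168), so a direction below 0 for the interferon list in KO does not hold with that correction. A larger number of the macrophages already present is argued against as the whole cause on these arrays. The interferon median exceeded the macrophage marker median by 0.752 (95% interval 0.353 to 1.24, members resampled). That interval holds no spread between samples. The macrophage markers were also mixed, with 8 of 13 above 0 and values from -1.66 (Cd163) to 0.73 (Adgre1), so a part played by macrophage number stays open. Chance differences between individual samples and a genotype-dependent response to Ang II cannot be told apart with 1 array per group, where the interferon median already differed by 0.269 between the untreated arrays, and a change in the state of macrophages was not tested.

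White adipocyte markers also moved in opposite directions, with a median of -0.4858 over 7 members in WT and 0.3018 over 6 in KO, where Adipoq and Retn are bounds; of the 4 measured on all arrays, Pnpla2 and Dgat2 went the other way, at 0.44 and 0.41 in WT and -0.04 and -0.14 in KO. Prr9 was at 1.131 in WT and -1.585 in KO, and Tada2a at 1.741 and -1.109, all as bounds.

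Genes at least 2-fold apart between KO and WT the same way without and with Ang II, measured on all 4 arrays, numbered 137. A sequence difference between the rats under a probe would change 1 probe of a gene and leave others alone. Of 22 such genes with a second probe, 13 moved the same way by 0.5 or more in that probe, or 59.1% (exact 95% interval 36.4% to 79.3%). Ccl20, Slpi, Ogn and Bex4 were among those where the probes moved together, and Csgalnact2, Dock9 and Rassf2 among those where they did not, all named after their values were seen. The share leaves open how much of the genotype difference is specific to single probes, and effects of the deletion and of strain background stay open beside it.

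Contractile genes were higher in KO, and several marker lists of other cells were lower. Scaling is argued against as the whole cause: of quantile normalization and normexp, normexp lowered the rise of the contractile median above that of all genes from 0.363 to 0.244 without Ang II (95% interval 0.0446 to 0.279, members resampled) and from 0.530 to 0.350 with it (0.176 to 0.465). A larger share of smooth muscle in the KO samples may contribute: 10 of 12 medians of 6 marker lists of other cells lay below 0 and none of 15 pairs of lists differed beyond its interval, but skeletal muscle markers stood at 0.10 and 0.07, and the intervals of that list and of the lymphatic list included 0. That explanation and a change of expression within cells cannot be told apart, since the lists are small and each group has 1 array.

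Probes with no gene name, which the comparisons do not use, also passed the 2-fold size rule. Higher and lower ones numbered 122 and 155 for Ang II in WT, 65 and 230 for Ang II in KO, 476 and 304 for KO against WT without Ang II and 358 and 317 with Ang II. For KO against WT they thus leaned higher where named genes leaned lower. For Ang II in WT they leaned lower where named genes, 198 higher and 98 lower, leaned higher.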

How the results depend on the processing

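The normexp correction and the percentile over detected probes were chosen after seeing the data; the other alternatives were fixed before. Of 198 recomputed counts and correlations, 136 stayed within 1.5 times (correlations within 0.1) and 62 did not. Of 492 list medians, 436 kept their side of the random range, 28 moved out of it, 25 moved into it, 1 changed sign and moved out of it and 2 reversed. Of 957 values of named genes, 879 stayed past 2-fold, 78 did not and none reversed. Of those 78, 76 came with normexp, where only 48 values stayed past 2-fold. The scalings to detected probes and the deposited table shift each array by about a constant, so they could move these values little.

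With normexp, whose offset of 50 is close to the arrays' 75th percentile signal and so shrinks ratios of dim genes, 29 genes were higher and 8 lower for Ang II in WT, 0 and 4 for Ang II in KO, 25 and 89 for KO against WT without Ang II, 18 and 137 with it, and 20 and 50 for the difference of responses, and 0 were lower in both responses. Lists that stood apart under normexp were 4 lower for Ang II in WT, 4 higher for KO against WT with Ang II and 6 lower for the difference. For the difference, the endothelial median became -0.0047 and the circadian clock median 0.0044, both reversed, and the cause was not tested.

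Among genes well above background on all 4 arrays, by construction a smaller set, 97 were higher and 30 lower for Ang II in WT, 10 and 40 in KO, and 156 and 238 for KO against WT without Ang II. With no filter on dim probes, which admits background noise, the counts were 719 and 795 for Ang II in WT, 392 and 797 in KO, 894 and 942 for KO against WT without Ang II, 654 and 1125 with it, and 1012 and 1467 for the difference, with 39 higher and 102 lower in both responses. At 1.5-fold they were 863 and 480, 299 and 364, 1064 and 1248, 888 and 1523, and 537 and 881 in the same order; at 3-fold they were 23 and 18, 3 and 26, 64 and 81, 24 and 99, and 14 and 37.

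Genes lower in both responses were 0 with quantile normalization and 0 with the mean of the gene's probes. Lists lower for Ang II in WT were 4 with quantile normalization, and lists lower for the difference were 6 with the mean of probes. The additive KO effect gave 558 higher and 715 lower with trended robust variances, 47 and 135 at an adjusted p under 0.1, 3 lower in the single-factor fit and 8 lower with the deposited value table; the cause was not tested. For Ang II every version gave 0.

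No paired analysis was possible because each group holds 1 array and the groups share only replicate number 1, so genotype alone served as the block in the additive fit. Leaving out an array would leave the additive fit no residual degree of freedom. The slide as a block was not run, since all arrays lay on 1 slide. Signal over background limits the dim genes, which are given as bounds in the single comparisons and entered the additive fit as read.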

Other observations

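No explanation was tested in this part. Of the immediate early list, Nr4a1, an orphan nuclear receptor, stood at 1.22 for Ang II in WT and -0.56 in KO, Nr4a2 at 0.92 and -0.47, and Nr4a3 at 0.80 and -0.34. All 3 were higher in KO than in WT without Ang II, at 1.22, 1.14 and 1.38. The immediate early list as a whole had a median difference of responses of -0.26 over 20 members (percentile 0.39) with 7 above 0, while Atf3 lay on the other side at 1.41; with normexp and with the mean of a gene's probes that median lay inside the random range. Complement genes had a median difference of -0.47 (percentile 0.18), with C2 at -1.27 and Cfb at -1.03, and C5ar1 at 1.37. Matrix proteases and inhibitors had one of -0.48 (percentile 0), with the plasminogen activators Plau at -1.31 and Plat at -1.23 and the protease Adamts4 at -1.24.

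Some further genes come from lists that did not stand apart in the comparisons given, and were chosen after their values were seen. In the insulin and IGF list, Igfbp3 stood at -1.25 for KO against WT both without and with Ang II. In the TGF-beta list, Il11 stood at 1.42 and 0.43 in these comparisons and Ccn2 at -0.89 and -1.01. Among nitric oxide, endothelin and prostanoid genes, Ptgs1 was at 1.34 and 0.88.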
